A study of Mus musculus with 15 samples.

How the data were processed

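Reduced representation bisulfite sequencing libraries of mouse bone marrow progenitors were analysed from the files the authors deposited, 1 per library, for 15 libraries in 7 groups. The authors' files list cytosines of CpGs by position and strand in the layout of the BSMAP methratio script, and per the submitters' processing notes reads were aligned with BSMAP 2.74 to mm9. The deposited values used for tests are counts, the number of methylated reads and the number of all reads at each cytosine, which stop at 65535. The deposited methylation fraction, methylated reads over all reads of the same row, was checked against the counts and not used further. The files carry no minimum of coverage, since cytosines with 1 read are present. Removal of duplicate reads, trimming and a measured bisulfite conversion rate are not given in the sources used here. Duplicate reads cut from the same restriction fragment cannot be told from separate molecules, so read counts overstate the number of molecules and binomial error understates the error of a level.

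All positions checked fell on CG in the NCBIM37 (mm9) reference, and the gencode vM1 annotation on the same build gave genes, exons and transcription start sites. The 2 gene models longer than 3000000 bp were not used to place regions. Reads of both strands of a CpG were added. CpGs on the 19 autosomes with at least 10 reads in all 15 libraries were kept (241527, or 114215 at 20 reads), with a median depth of 30 to 51 reads per library. They were grouped into windows of 1 kb with at least 3 such CpGs (29251 windows), here called regions, and into promoters, all such CpGs within 1 kb of an annotated start site of a gene (11849 promoters). For the gene lists the promoter with the most CpGs was used for each gene symbol. The level of a region in a library is its methylated reads over all its reads, and the error given is the SD over libraries. Level means per library weighted each CpG equally.

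Regions and promoters were tested with a quasi-binomial logistic model of methylated against all reads, with 1 mean for each of the 7 groups and 8 residual degrees of freedom. The dispersion of each region was estimated from Pearson residuals, squeezed towards a common value (prior degrees of freedom 5.33, median dispersion 2.45) and not allowed under 1. Contrasts were tested with an F test, and adjusted p-values are Benjamini-Hochberg over all regions or all promoters of a comparison. A region or promoter was called at an adjusted p under 0.05 and a difference of group means of at least 10 percentage points. Where both cell types entered, the groups had equal weight, and the effect of both mutations beyond the sum of the single ones was tested on the logit scale. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, with R 4.3.3, limma 3.58.1 and edgeR 4.0.16. Mean levels per library were compared with exact two-sided permutation tests of the libraries, restricted to within cell type or genotype where both entered.

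For places of called regions, Fisher's exact test compared them with the regions that could have been called, those whose second group lay at 90% or less for rises and at 10% or more for falls, and p-values were adjusted over 120 tests. Neighbouring regions were counted separately. The background was not matched for starting level, and all regions come from the same libraries, so these p-values do not measure the spread between libraries. The 9 gene lists (stem and early progenitor, erythroid and megakaryocyte, granulocyte and macrophage, lymphoid, DNA methylation machinery, leukaemia and tumour suppressor, developmental transcription factors, imprinted, and germline and retrotransposon defence) were fixed before the data were examined, as were the groups, the tests, the thresholds and the rule for named genes. List promoters were counted, adjusted over all promoters and over the list alone, and tested as sets with limma camera on log2 of methylated plus 1 over unmethylated plus 1 reads, with a preset correlation of 0.01 and with an estimated one. Named regions were, per comparison, drawn from the 10 largest rises and the 10 largest falls among called regions whose library values did not overlap between the groups, at most 1 per 10 kb, together with called list promoters. A region was given the gene whose promoter, exon, untranslated sequence or intron holds it, or else the gene with the nearest start site and its distance.

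The models were tested on simulated data with the depth and spread of these libraries, at 29251 regions of which 100 each changed by 10, 20 and 30 points. For double mutant against wild type MEP the quasi-binomial model found 31%, 76% and 90% of these and 3.62% of its calls were false, while limma found 16%, 44% and 63% and 0 of its 135 calls were false. edgeR found 34%, 79% and 93%, with 7.11% of its calls false. Alternatives tried were a minimum of 20 reads, 500 bp windows, a difference of 25 points, limma, the edgeR likelihood ratio test, a fit to the compared groups alone, GMP or all wild type libraries as the control of the double mutant, start sites with 500 bp either side, read-weighted means, the X chromosome included, replicates as a block and each library left out in turn. Where that left a group with 1 library, the spread came from the other groups. After the data were examined 2 more were added, the GMP and MEP libraries of a title prefix summed and each region's reads thinned to its shallowest library. The sex chromosomes and the mitochondrial genome were left out of the comparisons. They were used only for read shares and for the share of methylated mitochondrial reads, except that the X chromosome entered an alternative of the library means.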

Results

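DNA methylation was measured by reduced representation bisulfite sequencing. Bisulfite converts unmethylated cytosines, so the share of reads that stay unconverted at a CpG gives its methylation level, mostly in CpG-rich parts of the genome. The 15 mouse libraries came from bone marrow progenitors of 4 genotypes on a C57BL/6 background. The series title speaks of a methylation change in double mutant cells. Dnmt3a encodes an enzyme that places new DNA methylation. Idh2 R140Q is a leukaemia-associated form of a mitochondrial enzyme whose product, 2-hydroxyglutarate, inhibits enzymes that remove DNA methylation. Wild type cells (named so in the labels, with Mx1-cre and floxed Dnmt3a), Dnmt3a knockout cells and Idh2 R140Q cells (without Mx1-cre) were each sorted as granulocyte-macrophage progenitors (GMP) and as megakaryocyte-erythroid progenitors (MEP), with 2 libraries per genotype and cell type. Double mutant cells (Dnmt3a knockout with Idh2 R140Q) were malignant marrow progenitors sorted with the MEP surface markers, with 3 libraries, so they were compared with MEP. The labels call the samples biological replicates but do not state that they were separate animals. The sample titles tie each GMP library to an MEP library that may come from the same animal. The p-values therefore may measure only the spread between samples.

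The files held 30751438 to 35204906 reads over cytosines in wild type libraries and 28001420 to 31657332 in double mutant libraries. Knockout libraries had 20541812 to 26086791 and Idh2 mutant libraries 19306705 to 24587340. Comparisons used the 241527 autosomal CpGs with at least 10 reads in all 15 libraries, where the median depth was 30 to 51 reads per library. These CpGs filled 29251 regions of 1 kb on mouse build mm9, with a median of 4 CpGs per region and of 203 reads per region and library. Wild type libraries differed from all the others in their sex chromosome reads. Y chromosome reads came to 53.9 to 57.5 per 1000000 autosomal reads in wild type, 202.5 to 302.7 in knockout, 198.8 to 287.8 in Idh2 mutant and 357.1 to 386.3 in double mutant libraries. X chromosome reads came to 2.21% to 2.25% of the autosomal reads in wild type and to 1.17% to 1.47% in the other libraries. Every comparison of a mutant with wild type therefore also compares libraries that differ in sex chromosome content, and libraries that differ in depth. Double mutant libraries also held fewer reads than wild type MEP and more than single mutant MEP libraries, and their median depth was 39 to 45 reads against 50 to 51 in wild type MEP.

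Mean methylation over the common CpGs was 38.2% ± 1.07 (SD, n = 2) in wild type MEP, 39.1% ± 1.04 (n = 2) in knockout MEP, 39.3% ± 0.336 (n = 2) in Idh2 mutant MEP and 42.3% ± 0.619 (n = 3) in double mutant cells. In GMP it was 39.0% ± 0.138 in wild type, 38.4% ± 0.496 in knockout and 40.7% ± 0.575 in Idh2 mutant cells (SD, n = 2 each). The double mutant mean lay 4.15 points above wild type MEP, 3.25 above knockout MEP and 2.99 above Idh2 mutant MEP. Each of these differences had p = 0.1 (exact two-sided permutation test), the smallest that 3 against 2 libraries can give. Idh2 mutant libraries lay 1.44 points above wild type over both cell types (p = 0.0556, exact permutation within cell type, the smallest possible, and 0.25 after Benjamini-Hochberg adjustment over 10 tests). Knockout libraries lay 0.162 points above wild type (p = 0.889, exact permutation), a difference within the spread of libraries. Its sign changed without knockout GMP replicate 2 (-0.0130), knockout MEP replicate 2 (-0.206) or wild type MEP replicate 1 (-0.217). As methylated reads over all reads, which lets deep CpGs count for more, the knockout and Idh2 mutant differences became -4.92 and -3.08 points.

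**Figure D1:**
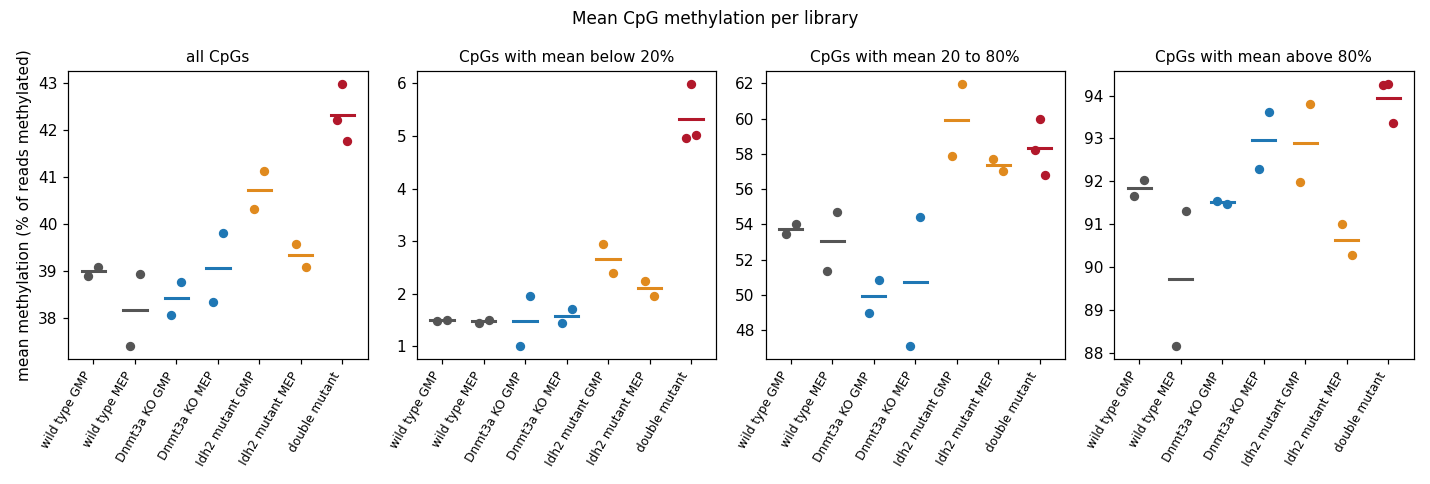
Mean methylation (percent, vertical axis) of the 7 groups over all common CpGs and over CpGs whose mean across groups was below 20%, 20% to 80% or above 80%; points are libraries and bars are group means. In CpGs below 20%, double mutant libraries lay between 4.97% and 5.99% and wild type libraries between 1.44% and 1.51%.

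The double mutant lay above wild type MEP in each of 3 classes of CpG, set by the mean across all 7 groups, the double mutant included. At the 129221 CpGs with a mean below 20%, methylation was 5.32% ± 0.579 (SD, n = 3) in double mutant cells and 1.47% in wild type MEP (n = 2). At the 28575 CpGs between 20% and 80% the means were 58.3% and 53.1%, and at the 83731 CpGs above 80% they were 94.0% and 89.7%. Against knockout MEP the double mutant differences in the 3 classes were 3.75, 7.57 and 1.00 points, and against Idh2 mutant MEP 3.22, 0.944 and 3.32 points. Libraries overlapped for knockout above 80% (p = 0.3) and for Idh2 mutant at 20% to 80% (p = 0.6), and the other 4 differences had p = 0.1 (exact permutation, the smallest possible). The 7.57 points became 3.94 without knockout MEP replicate 1, and the 1.00 point 0.330 and 1.67 without knockout MEP replicates 1 and 2. The 0.944 points became 0.108 and 1.72 without double mutant replicates 2 and 3, 0.604 without Idh2 mutant MEP replicate 2 and 0.276 at 20 reads per CpG. Above 80% the 4.22 points against wild type MEP became 2.66 without its replicate 1. Idh2 mutant cells exceeded wild type by 5.25 points in the intermediate class and by 0.901 points in the low class. All 4 Idh2 mutant libraries lay above all 4 wild type libraries in each (p = 0.0556, exact permutation, the smallest possible, 0.304 after adjustment over 70 class tests). Within the Idh2 mutant and within the knockout, libraries with more methylated mitochondrial reads, a rough measure of unconverted reads, also had higher low class levels. In the Idh2 mutant these reads came to 0.280% to 2.43%. Conversion may therefore move low class levels, though wild type libraries had 1.62% to 3.27% of such reads and lower levels. Knockout cells lay 3.06 points below wild type in the intermediate class (p = 0.167, exact permutation), and 1.24 and 4.88 points below without knockout MEP replicates 1 and 2.

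**Figure D2:**
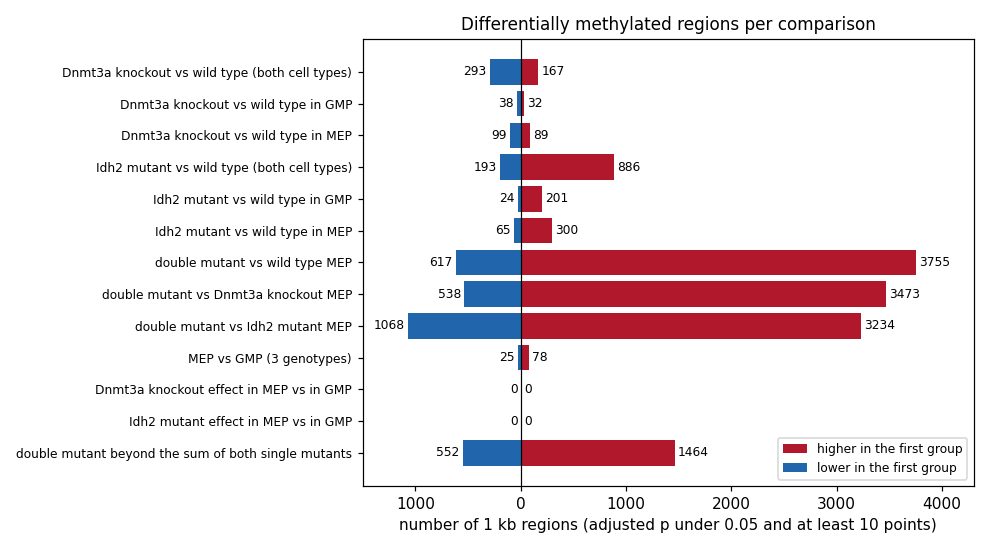
Number of 1 kb regions (horizontal axis) called higher (to the right) or lower (to the left) in each comparison, at an adjusted p under 0.05 and a difference of at least 10 points. The double mutant had 4372 called regions against wild type MEP, and the Idh2 mutant had 1079 and the knockout 460 over both cell types.

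Loss of Dnmt3a was examined first at the targeted gene, on chromosome 12 from 3806007 to 3914443. Reads in its window 3912001 to 3913000 came to 6.54 to 8.21 per 1000000 in wild type, 0.422 to 1.85 in knockout, 0 to 0.143 in double mutant and 0 to 1.19 in Idh2 mutant libraries. In the window 3902001 to 3903000, which holds coding exons, the values were 0.824 to 1.15, 0 to 0.213, 0 to 0.0669 and 0 to 0.311. Because the depth was also low in Idh2 mutant cells, whose labels leave Dnmt3a intact, and the labels do not name the deleted part, read depth did not check the knockout.

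Knockout cells had regions of both lower and higher methylation than wild type, over GMP and MEP together. An intron of Prdm16, a transcription factor needed by haematopoietic stem cells, fell from 61.6% ± 8.44 to 14.1% ± 11.4 (SD, n = 4 each, chromosome 4, 153918001 to 153919000, adjusted p = 0.0127). A window in the untranslated sequence of Sufu, which restrains Hedgehog signalling, fell from 75.6% ± 9.31 to 30.6% ± 7.33 (chromosome 19, 46530001 to 46531000, adjusted p = 0.000758). An intron of the transcription factor Nfix fell from 88.2% ± 6.28 to 42.1% ± 17.3 (chromosome 8, 87310001 to 87311000, adjusted p = 0.00102). The promoter of Hdac5, a histone deacetylase, fell from 61.8% ± 10.4 to 18.3% ± 6.70 (chromosome 11, 102086001 to 102087000, adjusted p = 0.0359). An intron of Lrrfip1, measured over 9 CpGs, fell by 42.7 points (chromosome 1, 92914001 to 92915000, adjusted p = 0.00102). Rises included an intron of Rnf157, from 42.7% ± 19.6 to 84.3% ± 3.43 (chromosome 11, 116267001 to 116268000, adjusted p = 6.31e-05). A coding exon of Utrn, the dystrophin relative utrophin, rose from 59.6% ± 4.37 to 91.1% ± 3.90 (chromosome 10, 12105001 to 12106000, adjusted p = 0.00107). A coding exon of Cdk8, a kinase of the Mediator complex, rose by 34.5 points (chromosome 5, 147111001 to 147112000, adjusted p = 0.00377). The largest fall, 55.0 points from 91.0% ± 1.17, lay 187898 bp from Ifng (chromosome 10, 118066001 to 118067000), in a window where the 11 libraries of the other genotypes together held 35.0% ± 14.4. Windows 57546 bp from Usp46 and 20566 bp from Gm16432 were likewise low outside wild type (30.9% and 47.9% against 78.5% and 94.9%).

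In all, 167 regions rose and 293 fell in the knockout over both cell types, with median differences of 18.5 and -21.4 points. Of the fallen regions, 33.4% lay within 1 kb of a start site, against 16.5% of the regions with room to fall by 10 points (odds ratio 2.61, Fisher's exact test, adjusted p = 4.13e-12). Of the risen regions, 11.98% did, against 59.2% of those with room to rise (odds ratio 0.0926, adjusted p = 1.02e-35). Of them 56.9% came from the regions of lowest CpG density against 21.5% (odds ratio 4.88). Here and in the later comparisons of place, starting levels were not matched. Regions with room to rise included many near 0%, as 12851 regions had a mean below 5% over the GMP groups. Regions higher in the knockout began at wild type means of 33.3% within GMP and 68.9% within MEP. Place and starting level therefore cannot be told apart. The count was 50 with limma, 165 of 14158 regions at 20 reads per CpG and 255 with the GMP and MEP libraries of each title prefix summed. It was 172 without knockout GMP replicate 1, 282 without knockout GMP replicate 2, 193 without knockout MEP replicate 1, 228 and 224 without wild type GMP replicates 1 and 2, and 280 without wild type MEP replicate 2. Prdm16, Hdac5, Cdk8 and the window near Usp46 did not pass with limma. Prdm16 and the window near Usp46 also did not pass without knockout GMP replicate 1 (adjusted p = 0.0597 and 0.0614) or wild type GMP replicate 2 (0.0863 and 0.0633). Prdm16 also did not pass without wild type MEP replicate 2 (0.0645), and the window near Usp46 without knockout MEP replicate 1 (0.0556). Hdac5 also did not pass without knockout GMP replicate 1 (adjusted p = 0.137) or 2 (0.0982), knockout MEP replicate 1 (0.153), wild type GMP replicate 2 (0.105) or wild type MEP replicate 2 (0.0796).

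Among promoters, 33 rose and 114 fell of 11849 tested. Of the 23 measured promoters of stem and early progenitor genes, 1 fell and none rose (2 fell when adjusted over the list alone). The Hoxa5 promoter held 84.5% ± 0.100 in wild type GMP, 87.7% ± 2.60 in wild type MEP, 54.4% ± 8.51 in knockout GMP and 52.7% ± 25.4 in knockout MEP (SD, n = 2 each, chromosome 6, 52154799 to 52154821, adjusted p = 0.0229). Of the 56 developmental transcription factor promoters, that of Foxa1, a factor of gut endoderm, fell by 16.0 points (1 adjusted over the list alone, chromosome 12, 58646736 to 58648061, adjusted p = 0.0196), and 8 of the 56 had a wild type level of 10% or more. Of the 6 lymphoid promoters, that of Vpreb1, part of the pre-B-cell receptor, rose by 11.7 points (1 adjusted over the list alone, chromosome 16, 16868853 to 16871416, adjusted p = 0.0382). None passed of 11 erythroid and megakaryocyte, 8 granulocyte and macrophage, 12 DNA methylation machinery, 31 leukaemia and tumour suppressor, 15 imprinted and 8 germline promoters (quasi-binomial model, with 1 higher and 1 lower granulocyte and macrophage promoter adjusted over the list alone). The stem and early progenitor and the developmental lists shifted downward with a preset correlation (limma camera, adjusted p = 0.0247 each), with adjusted p = 0.662 each with an estimated correlation. The promoter count was 41 without knockout GMP replicate 1, 37 without knockout MEP replicate 1, 330 without knockout MEP replicate 2, 40 and 75 without wild type GMP replicates 1 and 2, and 46 without wild type MEP replicate 2. Hoxa5 had adjusted p = 0.0831, 0.0953, 0.0813, 0.0517 and 0.122 without knockout GMP replicate 1, wild type GMP replicate 1 or 2, or wild type MEP replicate 1 or 2. The calls of Foxa1 and Vpreb1 ended without any 1 of 6 and of 7 of the 8 libraries.

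Within GMP alone 32 regions rose and 38 fell in the knockout, and within MEP alone 89 rose and 99 fell. At the 99 regions lower in knockout MEP, knockout GMP held 33.1%, wild type GMP 53.4% and Idh2 mutant GMP 49.6%. The GMP levels did not enter the difference tested, though all 15 libraries set the dispersion and GMP and MEP libraries may share animals. At the 89 higher ones they held 79.1%, 67.9% and 81.2%, so Idh2 mutant GMP had risen there as well. No region differed in its knockout effect between MEP and GMP in the quasi-binomial model (1880 had an unadjusted p under 0.05, edgeR called 29, limma 0, and 1 passed at 20 reads per CpG). The GMP count of 70 became 17 and 3 without knockout replicates 1 and 2, 21 and 14 without wild type replicates 1 and 2, 0 with limma, 165 with edgeR (60 of them higher) and 309 when fitted to the compared groups alone (77 higher, 232 lower). The MEP count of 188 became 2 and 319 without knockout replicates 1 and 2, 76 and 54 without wild type replicates 1 and 2, 1 with limma, 442 with edgeR (256 higher, 186 lower) and 1 when fitted to the compared groups alone. The balance of directions thus changed with the model.

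Most regions that differed between the Idh2 mutant and wild type were higher in the mutant, over GMP and MEP together. The promoter of Klra3, of the Ly49 receptors of natural killer cells, rose from 32.0% ± 7.18 to 78.7% ± 3.52 (SD, n = 4 each, chromosome 6, 130287001 to 130288000, adjusted p = 0.000111). The promoter of Abhd15 rose from 23.1% ± 6.16 to 69.1% ± 8.80 (chromosome 11, 77331001 to 77332000, adjusted p = 0.000208). A coding exon of the collagen gene Col5a1 rose from 8.58% ± 4.22 to 53.8% ± 14.3 (chromosome 2, 27777001 to 27778000, adjusted p = 0.000566). A window 8422 bp from Il10, which encodes an anti-inflammatory cytokine, rose from 42.4% ± 22.9 to 92.1% ± 6.09 (chromosome 1, 132907001 to 132908000, adjusted p = 0.00874). Falls included a window 9818 bp from Gipc2, from 72.0% ± 19.6 to 6.21% ± 4.93 (chromosome 3, 151755001 to 151756000, adjusted p = 0.000613). A coding exon of the delta opioid receptor gene Oprd1 fell from 74.6% ± 11.7 to 30.4% ± 11.4 (chromosome 4, 131669001 to 131670000, adjusted p = 0.00208). An intron of Tbx5, a heart and forelimb factor, fell from 39.1% to 2.54% (chromosome 5, 120316001 to 120317000). The windows near Ifng, Usp46 and Gm16432 described for the knockout were also among the 10 largest falls here. That near Usp46 did not pass without wild type GMP replicate 2 (adjusted p = 0.0534) or Idh2 mutant MEP replicate 2 (0.0567).

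In all, 886 regions rose and 193 fell in the Idh2 mutant over both cell types, with median differences of 19.9 and -17.3 points. Of the risen regions 24.9% lay within 1 kb of a start site against 59.2% of the regions with room to rise (odds ratio 0.217, Fisher's exact test, adjusted p = 1.67e-96). In introns lay 26.2% against 10.4% (odds ratio 3.26, adjusted p = 4.00e-40). Within GMP 201 rose and 24 fell, and within MEP 300 rose and 65 fell. At the 300 regions higher in Idh2 mutant MEP, wild type GMP held 29.5%, Idh2 mutant GMP 50.9% and knockout GMP 34.8%. At the 65 lower ones they held 66.8%, 48.65% and 52.5%, so knockout GMP had fallen there as well. Double mutant cells held 62.7% at these 65 regions and wild type MEP 66.0%. No region differed in its effect between the cell types in the quasi-binomial model (1081 had an unadjusted p under 0.05, edgeR called 1 and limma 0). The count of 1079 over both cell types became 357 with limma, 709 with libraries summed per title prefix, 682 and 652 without wild type GMP replicates 1 and 2, and 653 without Idh2 mutant GMP replicate 1. The GMP count of 225 became 0 with limma, 492 with edgeR, 3 and 0 without wild type GMP replicates 1 and 2 and 21 without Idh2 mutant GMP replicate 1. The MEP count of 365 became 1 with limma, 9 when fitted to the compared groups alone, 202 and 59 without wild type MEP replicates 1 and 2 and 78 without Idh2 mutant MEP replicate 2.

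Of 11849 promoters, 182 rose and 83 fell in the Idh2 mutant. The promoter of Hlf, a transcription factor of haematopoietic stem cells, held 25.9% ± 0.857 in wild type GMP, 18.1% ± 0.616 in wild type MEP, 44.4% ± 6.03 in mutant GMP and 31.8% ± 11.1 in mutant MEP (SD, n = 2 each, chromosome 11, 90242841 to 90252354, adjusted p = 0.0162). Hlf was the only one of the 23 stem and early progenitor promoters to pass (1 adjusted over the list alone). Csf2ra, which encodes a chain of the GM-CSF receptor, was the only one of 8 granulocyte and macrophage promoters to rise, by 22.9 points (1 adjusted over the list alone, chromosome 19, 61303938 to 61304437, adjusted p = 0.00889). Vpreb1 was the only one of 6 lymphoid promoters to rise, by 18.7 points (1 adjusted over the list alone, adjusted p = 0.00372), and Foxa1 the only one of 56 developmental promoters to pass, where it fell by 13.5 points (1 adjusted over the list alone, adjusted p = 0.0350). No promoter passed in the erythroid and megakaryocyte, DNA methylation machinery, leukaemia and tumour suppressor, imprinted and germline lists, and no list passed as a set with limma camera. The promoter count of 265 became 107 and 157 without wild type GMP replicates 1 and 2, 159 without wild type MEP replicate 2 and 104 without Idh2 mutant GMP replicate 1. Without Idh2 mutant GMP replicate 1, Csf2ra had adjusted p = 0.107, and the call of Foxa1 ended without any 1 of 6 of the 8 libraries. Hlf had adjusted p = 0.0604, 0.0505 and 0.0603 without wild type GMP replicate 1, wild type MEP replicate 2 or Idh2 mutant GMP replicate 2.

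Double mutant cells differed from wild type MEP at 4372 regions, 14.95% of those tested. Of these 3755 rose and 617 fell. The promoter of Sept10, a septin, rose from 5.52% ± 3.59 (SD, n = 2) to 93.4% ± 3.30 (SD, n = 3, chromosome 10, 58685001 to 58686000, adjusted p = 1.04e-07). A coding exon of the protocadherin gene Pcdh10 rose from 1.86% ± 0.516 to 84.5% ± 3.13 (chromosome 3, 45184001 to 45185000, adjusted p = 1.06e-07). The promoter of Nptx2, a neuronal pentraxin, measured over 11 CpGs, rose from 7.35% ± 1.18 to 79.7% ± 1.82 (chromosome 5, 145306001 to 145307000, adjusted p = 8.79e-08). The promoter of Hoxd11, a patterning gene, rose from 10.5% ± 7.96 to 84.8% ± 5.51 (chromosome 2, 74519001 to 74520000, adjusted p = 7.52e-06). A window 5292 bp from Pax3, a neural crest and muscle factor, rose by 76.3 points (chromosome 1, 78199001 to 78200000). Falls included a window 21393 bp from Cd300a, an inhibitory receptor of myeloid cells, from 81.0% ± 6.11 to 1.09% ± 1.40 (chromosome 11, 114773001 to 114774000, adjusted p = 3.21e-07). An intron of Myof, which encodes myoferlin, fell from 83.6% ± 0.983 to 12.01% ± 3.40 (chromosome 19, 37993001 to 37994000, adjusted p = 2.04e-06). An intron of Pstpip2, an adaptor of macrophages and neutrophils, fell from 67.5% ± 1.11 to 2.78% ± 2.35 (chromosome 18, 78042001 to 78043000, adjusted p = 2.83e-05). At the 3755 risen regions the single mutant MEP means were 28.5% in knockout and 30.6% in Idh2 mutant cells, against 26.9% in wild type MEP and 50.6% in double mutant cells.

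Median differences were 20.7 points at the risen and -21.6 points at the fallen regions. Risen regions lay within 1 kb of a start site in 49.2% of cases against 57.4% of the regions with room to rise (odds ratio 0.674, Fisher's exact test, adjusted p = 3.41e-27). Fallen regions did in 22.2% against 16.4% of those with room to fall (odds ratio 1.48, adjusted p = 0.000325). The count was 1964 of 14158 regions at 20 reads per CpG and 1605 for differences of at least 25 points. Without any 1 library it lay between 3540 and 4072.

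Itga2b, which encodes the megakaryocyte and platelet integrin CD41, changed in both directions within its gene on chromosome 11. The window 102317001 to 102318000, at an annotated internal start site, rose from 2.81% ± 2.40 in wild type MEP to 74.3% ± 8.54 in double mutant cells (adjusted p = 8.96e-07). The window 102329001 to 102330000, which lies 488 bp from another start site, fell from 81.5% ± 5.67 to 9.99% ± 5.74 (adjusted p = 4.19e-07, SD, n = 2 and 3). Over the 16 CpGs near all its annotated start sites together the level was 17.6% ± 2.41 in wild type MEP and 32.2% ± 2.83 in double mutant cells, a rise of 14.6 points (adjusted p = 0.00106).

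**Figure D3:**
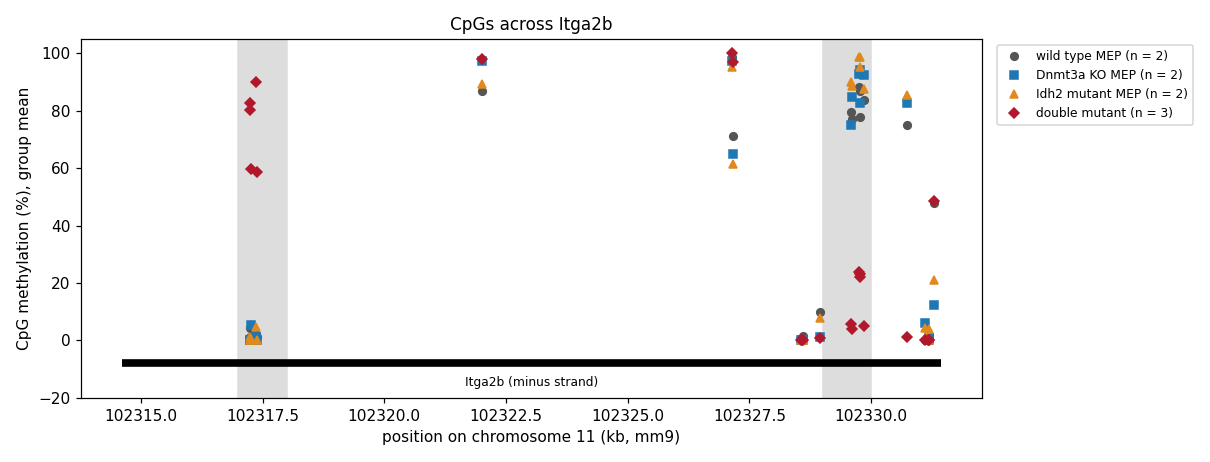
Methylation (percent, vertical axis) of single CpGs by group along Itga2b on chromosome 11 (mouse build mm9, position on the horizontal axis); points are group means, grey bands the windows starting at 102317001 and 102329001. Double mutant cells lay at 74.3% in the first window and 9.99% in the second, wild type MEP at 2.81% and 81.5%.

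Of 11849 promoters, 1392 rose and 74 fell in double mutant cells against wild type MEP. Promoters of developmental transcription factors rose in 31 of 56 cases and fell in none (31 adjusted over the list alone), with a median difference of 12.7 points. Of the 56, 7 had a wild type MEP level of 10% or more and so had room to fall. Irx2 rose from 2.89% ± 0.880 (SD, n = 2) to 53.3% ± 4.94 (SD, n = 3, chromosome 13, 72765871 to 72769392, adjusted p = 4.98e-08). Sox2, a factor of embryonic and neural stem cells, rose from 3.12% ± 0.133 to 35.6% ± 4.68 (chromosome 3, 34548730 to 34550050, adjusted p = 3.39e-07). Otx2 and Pax1 rose by 35.8 and 35.3 points. As a set the list shifted upward (limma camera, adjusted p = 6.37e-16 with a preset correlation, 0.0356 with an estimated correlation). Of 31 leukaemia and tumour suppressor promoters 5 rose (6 adjusted over the list alone) and none fell. These were Sfrp1, a secreted Wnt antagonist, from 0.476% ± 0.673 to 56.9% ± 2.87 (chromosome 8, 24521909 to 24522035, adjusted p = 2.24e-07), and Wt1, from 18.9% ± 4.75 to 68.1% ± 9.997 (chromosome 2, 104967469 to 104970719, adjusted p = 6.02e-06). The others were Id4, from 2.21% to 40.0%, Cdh1, which encodes E-cadherin, by 17.2 points, and the Wnt inhibitor Wif1, by 12.9 points. Of 15 imprinted promoters 2 rose (3 adjusted over the list alone), Dlk1 by 45.7 and Grb10 by 37.3 points. No list other than the developmental one passed as a set (limma camera, adjusted p of 0.254 or more with a preset correlation). For the leukaemia and tumour suppressor list it was 0.634, with a median difference of 0.406 points. Its rises stand beside the 1392 of all 11849 promoters that rose.

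Among blood lineage promoters, of 11 erythroid and megakaryocyte promoters 3 rose in double mutant cells (3 adjusted over the list alone). Rhd, a red cell blood group gene, rose by 24.2 points and Ank1, the red cell ankyrin, by 12.9 points. Itga2b rose over all its start sites together as above, through CpGs near its internal start site and not those towards its upstream end. Of 8 granulocyte and macrophage promoters 2 rose (2 adjusted over the list alone), Mmp9, a neutrophil gelatinase, by 21.7 and Fcgr3, which encodes CD16, by 17.0 points. Of 6 lymphoid promoters the T-cell factor gene Bcl11b rose, by 19.96 points (1 adjusted over the list alone). Of 23 stem and early progenitor promoters Hoxa7 and Nkx2-3 rose, by 12.5 and 10.5 points (2 adjusted over the list alone). Of 8 germline promoters Asz1 rose by 10.5 points (1 adjusted over the list alone), and none of 12 DNA methylation machinery promoters passed, in the quasi-binomial model. Rhd (adjusted p = 0.0907 without wild type MEP replicate 1), Mmp9 and Cdh1 (0.0943 and 0.0735 without wild type MEP replicate 2) did not pass without that library. Hoxa7 differed by less than 10 points without double mutant replicate 3 (9.10), and the calls of Nkx2-3 and Asz1 ended without any 1 of 4 of the 5 libraries.

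**Figure D4:**
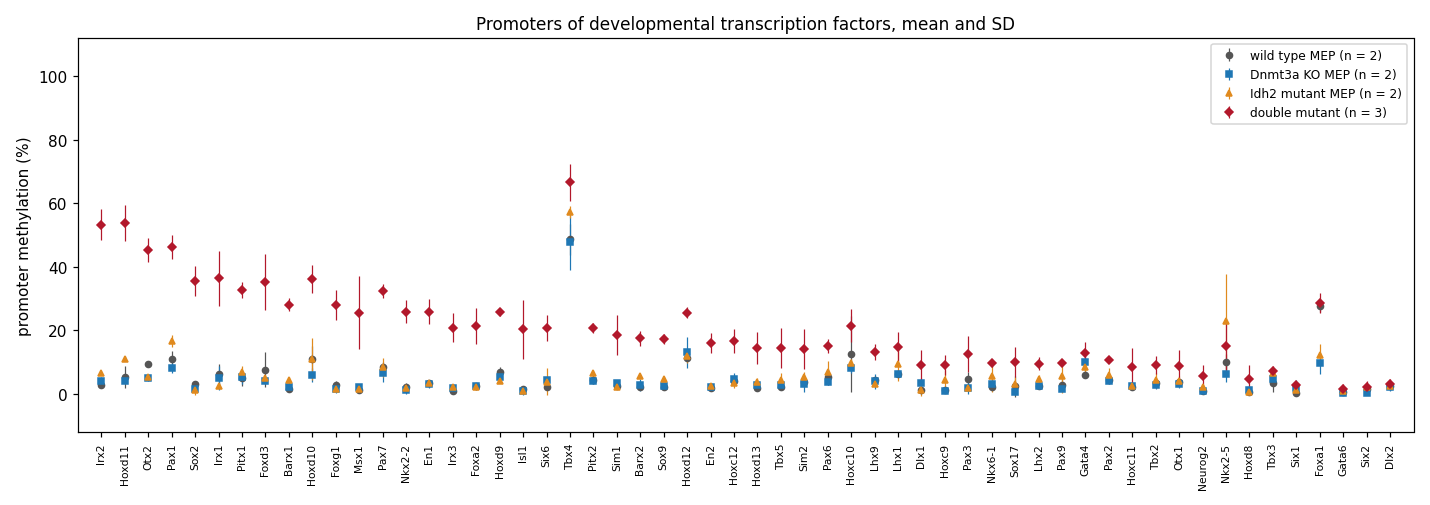
Promoter methylation (percent, vertical axis) of the 56 measured developmental transcription factors in wild type, knockout and Idh2 mutant MEP (n = 2 each) and double mutant cells (n = 3); points are means and bars are SDs. Irx2 and Hoxd11 reached 53.3% and 53.7% in double mutant cells, and 2.89% and 5.36% in wild type MEP.

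Against the single mutants, which had a sex chromosome share nearer to that of the double mutant, double mutant cells also differed at many regions. Against knockout MEP 3473 regions rose and 538 fell, and against Idh2 mutant MEP 3234 rose and 1068 fell. Sept10, Pcdh10, Olfm2, Cacng4 and the window near Pax3 were among the 10 largest rises in both and against wild type. Ptger1, a prostaglandin E receptor gene, held 91.5% ± 2.12 (SD, n = 3) in a coding exon in double mutant cells, 7.24% ± 3.58 in knockout and 8.42% ± 6.95 in Idh2 mutant MEP (SD, n = 2 each, chromosome 8, 86192001 to 86193000, adjusted p = 1.00e-04 and 0.000101). A coding exon of Csf2ra rose from 8.36% ± 9.10 in knockout MEP to 88.8% ± 3.55 (chromosome 19, 61301001 to 61302000, adjusted p = 4.00e-06). One of the neuronal kinase gene Brsk1 rose from 4.33% ± 6.12 in Idh2 mutant MEP to 95.5% ± 1.32 (chromosome 7, 4658001 to 4659000, adjusted p = 2.12e-05). The Itga2b window 102329001 to 102330000 fell against both, by 78.2 and 82.4 points. An intron of Fbxo31 held 2.48% ± 1.48 in double mutant cells, 66.3% ± 0.502 in knockout and 87.9% ± 7.36 in Idh2 mutant MEP (chromosome 8, 124094001 to 124095000, adjusted p = 8.27e-07 and 4.28e-07). A window 62143 bp from Lmo2, a cofactor of blood cell formation, fell by 55.8 points against knockout MEP (chromosome 2, 103735001 to 103736000). The window near Il10 that was raised in Idh2 mutant cells fell from 97.2% ± 2.56 to 1.79% ± 2.72 against them (adjusted p = 6.93e-05).

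Of 11849 promoters 1669 rose and 98 fell against knockout MEP, and 1366 rose and 199 fell against Idh2 mutant MEP. Of the 56 developmental promoters 35 rose against knockout (35 adjusted over the list alone) and 31 against Idh2 mutant MEP (32 adjusted over the list alone), and none fell. As a set they shifted upward in both (limma camera, adjusted p = 5.18e-16 and 4.83e-13 with a preset correlation), with adjusted p = 0.0350 and 0.0626 with an estimated correlation, so the second did not hold. No other list passed as a set against either (limma camera, adjusted p of 0.278 or more and 0.184 or more with a preset correlation). Leukaemia and tumour suppressor promoters rose in 7 and 6 of 31 cases (7 and 6 adjusted over the list alone), Sfrp1 by 52.5 and 54.0 points and Wt1 by 59.5 and 45.2 points. Imprinted promoters rose in 4 and 2 of 15 (5 and 2 adjusted over the list alone), stem and early progenitor promoters in 4 and 1 of 23 (4 and 1, with 1 lower against Idh2 mutant MEP, adjusted over the list alone). The counts were 2 and 3 for the 11 erythroid and megakaryocyte promoters, and 2 and 2 for the 8 granulocyte and macrophage promoters, with the same counts adjusted over the list alone. The lymphoid gene Vpreb1 fell by 11.7 and 14.0 points, while 2 and 1 of the 6 lymphoid promoters rose. The Dnmt3a promoter rose by 15.4 points against knockout MEP (adjusted p = 0.0380), a call that ended without knockout MEP replicate 1 (adjusted p = 0.395) or any 1 double mutant library (0.107, 0.0613 and 0.0808). The remaining machinery promoters and all germline promoters did not pass.

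The double mutant departed from the sum of the single mutant effects at 2016 regions (DM minus knockout minus Idh2 mutant plus wild type MEP). The p-value was from the logit scale, while direction and smallest difference were read from group means in percent, and these need not match. In percent, 1464 regions were higher and 552 lower than the sum, with a median departure of 31.4 and -29.4 points. For promoters the counts were 1033 higher and 144 lower. Developmental transcription factor promoters made up 21 of the higher ones and none of the lower (25 adjusted over the list alone), with a median of 11.8 points over the list. Other lists had higher promoters too, 4 leukaemia and tumour suppressor, 3 erythroid and megakaryocyte, 2 machinery, 1 stem and early progenitor and 1 imprinted. The granulocyte and macrophage list had 2 higher and 1 lower, and the lymphoid list 1 higher and 1 lower. The list as a set had adjusted p = 1.83e-11 with a preset correlation and adjusted p = 0.0884 with an estimated correlation (limma camera). The region count became 1205 with limma, 1179 without knockout MEP replicate 1 and 1142 without wild type MEP replicate 2, and the promoter count 747 and 678 without these libraries. This contrast sets wild type and double mutant libraries, which held more reads over cytosines, against the single mutant libraries, which held fewer. A difference tied to read number, or a batch that follows it, therefore cannot be told apart from a joint effect of the mutations.

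Between cell types, MEP and GMP of the 3 genotypes differed at 103 regions, 78 higher and 25 lower in MEP. Regions of low CpG density made up 73.1% of the higher ones against 19.8% of those with room to rise (odds ratio 11.1, Fisher's exact test, adjusted p = 5.39e-23). An intron of Alas1, which encodes the first enzyme of haem synthesis outside red cells, held 89.1% ± 11.3 in MEP and 50.1% ± 11.4 in GMP (SD, n = 6 each, chromosome 9, 106148001 to 106149000, adjusted p = 0.00148). An intron of Snx18 held 76.9% ± 16.9 and 30.7% ± 17.5 (chromosome 13, 114404001 to 114405000, adjusted p = 0.000501). The promoter of the interferon-induced gene Ifitm2 held 44.3% ± 8.47 and 19.4% ± 7.27 (chromosome 7, 148142001 to 148143000, adjusted p = 0.00274). The promoter of Stat5a, a signal transducer of cytokine receptors, was lower in MEP, at 46.0% ± 9.63 against 77.4% ± 11.96 (chromosome 11, 100741001 to 100742000, adjusted p = 0.00255). That of Lrpprc was lower as well, at 43.1% ± 19.2 against 82.3% ± 8.49 (chromosome 17, 85176001 to 85177000, adjusted p = 0.00235). With limma the count was 44 and Ifitm2 did not pass, and edgeR called 191. With the shared title prefix as a replicate block the count was lower still, and 4 named regions passed while 11 did not. Snx18 passed with this block, and Alas1, Ifitm2, Stat5a and Lrpprc did not.

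Of 11849 promoters 7 were higher and 2 lower in MEP. Rhd, of the red cell list, was 27.7 points lower, 1 of 11 erythroid and megakaryocyte promoters (1 adjusted over the list alone), at 64.0%, 76.1% and 34.6% in wild type, knockout and Idh2 mutant MEP against 91.5%, 78.9% and 87.2% in GMP (chromosome 4, 134420494 to 134420671, adjusted p = 0.0398). That call ended without any 1 of 10 of the 12 libraries. No promoter passed in the other 8 lists in the quasi-binomial model, with 1 higher granulocyte and macrophage promoter adjusted over the list alone. The granulocyte and macrophage and the lymphoid lists shifted upward in MEP as sets (limma camera, adjusted p = 0.00277 and 0.00828), with adjusted p = 0.171 each with an estimated correlation. The count of 9 promoters became 0 without knockout GMP, wild type GMP, Idh2 mutant GMP or Idh2 mutant MEP replicate 1 or without Idh2 mutant MEP replicate 2, 1 without wild type GMP or Idh2 mutant GMP replicate 2, 3 without wild type MEP replicate 1 and 4 without knockout MEP replicate 2.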

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

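All tests of explanations given here were chosen after the result was seen, except the counts of other splits of the libraries, which were set before.

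Double mutant cells gained methylation at regions that were low elsewhere, and 3755 regions were higher than in wild type MEP. Unconverted cytosines would raise all low regions. Yet 55.4% of the 11470 regions below 5% in every other group stayed below 1% in all 3 double mutant libraries. In both wild type MEP libraries 74.8% did. Methylated mitochondrial reads, a rough measure from few CpGs, came to 0.912% to 1.56% in double mutant and 1.62% to 3.27% in wild type libraries. Both argue against incomplete conversion as the whole cause. A difference of the wild type libraries from all others would place the single mutants near the double mutant, but both single mutant MEP means lay nearer to the double mutant at 8.28% of these regions. After thinning to equal depth 84.3% of the higher calls were left, so most of them did not hinge on unequal read numbers. Thinning draws from the same reads and keeps their expected levels, so it cannot test a bias that came with depth. A biological effect of both mutations, a library batch of the double mutant's own, a bias linked to depth, and a different mix of cells in the malignant marrow remain open. The double mutant was the only malignant group and had no GMP sort.

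Idh2 mutant regions were split by direction, and read in the cell type whose levels did not enter the call, though its libraries helped to set the dispersion and may come from the same animals. At the 300 regions higher in MEP, Idh2 mutant GMP lay 21.4 points above wild type GMP and knockout GMP 5.29 points, a share of 24.7% (18.1% to 31.0%, 95% bootstrap over regions). Such intervals hold the spread between regions in the same libraries, not the spread between libraries or animals. What is read from them holds for these libraries only. At the 201 higher in GMP the shares in MEP were 22.2% for knockout (15.05% to 29.5%) and 39.8% for double mutant cells (28.7% to 51.3%), so the knockout values argue against depth or sex shared by the mutants as the whole cause of the gain, while a part of this size may come from them. At the lower regions the knockout share was 79.0% (60.8% to 98.5%) for the 65 of MEP and 75.4% (61.1% to 88.8%) for the 24 of GMP, which is consistent with a difference that both single mutants share, such as depth or batch, but the double mutant share at the 24 was 17.1% (-11.3% to 42.0%), which argues against wild type libraries standing apart from every mutant, as by sex. An effect of the Idh2 mutation and a batch of these mice stay open in both directions, and neither was tested.

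Knockout regions were read in the same way, with the share that other mutants had of the knockout difference. The intervals again leave out the spread between libraries or animals. At the 32 regions higher in GMP the shares in MEP were 140.7% for Idh2 mutant (22.9 against 16.2 points, 113.5% to 176.3%, 95% bootstrap over regions) and 98.6% for double mutant cells (74.8% to 121.8%), which is consistent with wild type libraries that stand apart from every mutant, by sex, animals or batch, and at the 89 higher in MEP the Idh2 mutant share in GMP was 118.9% (102.9% to 140.3%). At the 99 regions lower in MEP, Idh2 mutant GMP lay at -3.78 and knockout GMP at -20.3 points from wild type, a share of 18.6% (3.44% to 33.7%), which argues against a difference shared by both single mutants as the whole cause there. At the 38 lower in GMP the shares were 43.5% for Idh2 mutant (-8.51 against -19.6 points, 17.8% to 70.9%) and 56.0% for double mutant cells (22.0% to 86.0%), so for these an effect of the knockout and wild type libraries standing apart cannot be told apart, because the intervals hold shares on either side of 50%. A batch of the knockout mice stays open for all lower regions.

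Chance groupings of libraries were counted as other splits of the same libraries, each fitted to those libraries alone. For the knockout 1 of 35 splits, the real one, gave 331 calls and the highest other gave 0. For the Idh2 mutant 1 of 35 gave 911 and the highest other 1, and for the double mutant against all 4 wild type libraries 1 of 35 gave 4434 and the highest other 0. For MEP against GMP 1 of 100 splits drawn from 462 gave 74 and the highest other 13. The splits argue against chance for these 4 results only if each library is an independent sample, which the labels do not state. The real split parted 0 title prefix pairs for the knockout, the Idh2 mutant and the double mutant, and 6 for MEP against GMP. Few other splits parted the same number of pairs as the real one. There were 2 each for the knockout and the Idh2 mutant (at most 0 and 1 calls). For MEP against GMP there were 5 and for the double mutant 6, with 0 calls. If libraries of one prefix share animals, these are too few to exclude chance. A batch that follows the groups is not excluded.

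The mean methylation differences of the knockout from wild type were -0.575 points in GMP and 0.900 points in MEP. They went opposite ways in the group means, and the difference between them was not tested. With read-weighted means both were negative, at -3.60 and -6.24 points. The GMP value became -0.224 and -0.926 without knockout replicates 1 and 2, and the MEP value 1.64 and 0.162 without knockout replicates 1 and 2 and 0.140 and 1.66 without wild type replicates 1 and 2. The departure of the double mutant from the sum of both single mutants, called at 2016 regions, was picked up as an effect of one mutation that differed with the other. Read number differed in the same way, higher in wild type and double mutant than in single mutant libraries, so the 2 cannot be told apart. Y chromosome reads, which no comparison used, came to about 203 per 1000000 autosomal reads in the lowest knockout library, 199 in the lowest Idh2 mutant and 357 in the lowest double mutant library, against 57.5 in the highest wild type library.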

How the results depend on the processing

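Summing the libraries of a title prefix and thinning reads were chosen after the data were examined, and all other alternatives before. The cause of a change of a count was not tested. Alternatives not listed, among them GMP or all wild type libraries as the control of the double mutant, gave counts within 1.5 times the main ones in the same direction. The X chromosome was included only in library means, and no region or promoter count was made with it.

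At 20 reads per CpG 14158 regions were left, and calls were 165 for the knockout over both cell types, 23 in GMP and 69 in MEP, 469 for the Idh2 mutant over both cell types, 91 in GMP and 181 in MEP. The double mutant had 1964 calls against wild type, 1847 against knockout and 2006 against Idh2 mutant MEP, and 872 beyond the sum of the single mutants. MEP against GMP had 44, and 1 region had a knockout effect that differed between MEP and GMP.

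With 25 points as the smallest difference, calls were 132 for the knockout over both cell types and 61 in MEP, and 305 for the Idh2 mutant over both cell types, 124 in GMP and 198 in MEP. The double mutant had 1605, 1730 and 1750 against wild type, knockout and Idh2 mutant MEP and 1327 beyond the sum, and MEP against GMP had 46. With 500 bp windows the knockout had 43 in GMP.

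limma called 50 regions for the knockout over both cell types, 0 in GMP and 1 in MEP, 357 for the Idh2 mutant over both cell types, 0 in GMP and 1 in MEP, 44 for MEP against GMP and 1205 beyond the sum. Of the 3755 regions higher in double mutant than wild type MEP it kept 2787 and the edgeR likelihood ratio test 3577. The latter called 165 for the knockout in GMP, 442 in MEP, 492 for the Idh2 mutant in GMP, 191 for MEP against GMP, and 29 and 1 for knockout and Idh2 mutant effects that differed between cell types. A fit to the compared groups alone, with fewer libraries for the spread, called 309 for the knockout in GMP, 1 in MEP and 9 for the Idh2 mutant in MEP.

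Summed libraries gave 255 for the knockout and 709 for the Idh2 mutant. Thinned reads gave 29 for the knockout in GMP, 42 in MEP and 168 for the Idh2 mutant in MEP.

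With the replicate number as a replicate block, the knockout in MEP had 78 calls and the Idh2 mutant in GMP 135, and with a replicate block of the shared title prefix MEP against GMP had 22 (19 higher, 3 lower), with 4 of its 15 named regions among the calls. Of the 5 that the text describes, Snx18 passed (adjusted p = 0.0163), and Alas1, Ifitm2, Lrpprc and Stat5a did not with this replicate block (0.0758, 0.0741, 0.0549 and 0.160). The residuals of GMP and MEP libraries with one title prefix had correlations of 0.361 in wild type, -0.0397 in knockout and 0.510 in Idh2 mutant. Those of the same number in different genotypes had correlations of -0.0350 to 0.0493. Libraries of one title prefix thus shared deviations in wild type and Idh2 mutant, though not in knockout. GMP and MEP libraries may therefore not be independent samples. The replicate numbers did not pair libraries of different genotypes.

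Read-weighted library means turned the differences to -4.92 points for the knockout over both cell types and -6.24 in MEP, and to -3.08 for the Idh2 mutant over both cell types, -2.33 in GMP and -3.82 in MEP.

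Start sites with 500 bp either side gave 87 promoters for the knockout over both cell types, 3 in GMP and 24 in MEP, 157 for the Idh2 mutant over both cell types, 35 in GMP, and 5 for MEP against GMP. With an estimated correlation the adjusted p was 0.662 for stem and developmental factor promoters in the knockout, 0.0626 for developmental factors in double against Idh2 mutant MEP, 0.171 for granulocyte and lymphoid promoters in MEP against GMP and 0.0884 for developmental factors beyond the sum.

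With each library left out in turn, calls for the knockout ranged from 172 (without GMP 1) to 611 (without MEP 2) over both cell types, 3 to 21 in GMP and 2 to 319 in MEP. For the Idh2 mutant they ranged from 652 to 977, 0 (without wild type GMP 2) to 311 in GMP and 59 to 293 in MEP, and beyond the sum from 1142 to 1927. Promoter calls ranged from 37 to 330, 1 to 2 in GMP and 2 to 345 in MEP for the knockout, 104 to 317, 1 to 294 in GMP and 5 to 29 in MEP for the Idh2 mutant, 0 to 8 for MEP against GMP and 678 to 1376 beyond the sum.

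The mean difference of the knockout over both cell types ranged from -0.217 to 0.542 points. At CpGs under 20% it ranged from -0.191 to 0.279 over both cell types, -0.482 to 0.457 in GMP and -0.0375 to 0.239 in MEP, and between 20% and 80% in MEP from -5.94 to 1.34. The Idh2 mutant difference in MEP above 80% ranged from -0.663 to 2.48, and MEP against GMP between 20% and 80% from -2.02 to 0.405.

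Named regions were not followed with 500 bp windows or the X chromosome included, and at 20 reads only where enough CpGs were left (5 of the 20 for the double mutant against wild type MEP). Where followed, they were still called in 1577 cases and kept their direction but did not pass in 90. Called list promoters were followed only with each library left out, where they were still called in 729 cases and did not pass in 107. The sign reversed in 0 of these cases. For named regions this was largely set by their choice, since their library values did not overlap between the groups. Leaving out a library therefore could not reverse their sign. A change of model or of the smallest difference does not alter the group means either. Named regions were also picked for the largest differences, which favours passing a larger smallest difference. The 1577 cases therefore overstate how well calls hold.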

Other observations

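Regions set apart from all other libraries by at least 10 points show which genotype carried patterns of its own. Among 29251 regions the 3 double mutant libraries lay above all 12 others at 1372 and below them at 116, and the 4 Idh2 mutant libraries above all 11 others at 76 and below at 3. The 4 knockout libraries lay above the others at 0 and below at 15, and the 4 wild type libraries above at 6 and below at 2. Group sizes differ, so the counts are not on one scale. The 8 wild type regions include an intron of Trpc7, a calcium channel gene, at 44.7% ± 4.88 in wild type (SD, n = 4) and 78.0% ± 10.5 in the others (SD, n = 11, chromosome 13, 56972001 to 56973000), besides the windows near Ifng, Usp46 and Gm16432.

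Regions were put into classes by their mean over the 3 GMP groups, which hold no library of the comparison with the double mutant, a choice made after the data were seen. In the 2359 regions between 5% and 20%, double mutant cells held 22.4% ± 1.84 (SD, n = 3), wild type MEP 9.72% ± 0.444, knockout MEP 7.75% ± 1.62 and Idh2 mutant MEP 12.95% ± 0.104 (SD, n = 2 each). In the 12851 regions below 5% the double mutant mean was 3.87% and that of wild type MEP 0.800%, and in the 10232 regions above 80% they were 92.4% and 89.2%. In the 1449 regions between 20% and 50% knockout MEP held 28.1%, wild type MEP 33.65%, Idh2 mutant MEP 38.6% and double mutant cells 39.9%.

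Regions called in GMP of a single mutant were looked up in MEP calls, which compare other libraries, though all calls share the dispersion and GMP and MEP libraries may share animals. Of 201 regions higher in Idh2 mutant GMP, 69 were also higher in the double mutant against wild type MEP, where 25.8 would be shared if the calls were independent. Their mean was 41.9% in double mutant cells, 55.2% in Idh2 mutant MEP, 38.0% in knockout MEP and 33.05% in wild type MEP. Of these 201 regions 45 were also higher in the double mutant against knockout MEP (23.9 if independent), and of the 24 regions lower in Idh2 mutant GMP 5 were lower in the double mutant against wild type MEP (0.506 if independent) and 1 against knockout MEP (0.441 if independent). Of 38 regions lower in knockout GMP, 15 were also lower in the double mutant against wild type MEP (0.801 if independent), 12 in Idh2 mutant MEP (0.0844 if independent) and 9 in the double mutant against Idh2 mutant MEP (1.39 if independent). Of 32 regions higher in knockout GMP, 15 were also higher in the double mutant (4.11 if independent), 15 in Idh2 mutant MEP (0.328 if independent) and 1 in the double mutant against Idh2 mutant MEP (3.54 if independent). The values if independent took all 29251 regions, not only those with room to change. For falls the 12851 regions with a GMP mean below 5% had little room. These values are therefore too low, and the excess over them is overstated.

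A hypothesis from these data is that the double mutant holds the Idh2 mutant gain only in part. At the 201 regions higher in Idh2 mutant GMP, double mutant cells lay 8.81 points above wild type MEP, 39.8% of the Idh2 mutant MEP difference (28.7% to 51.3%, 95% bootstrap over regions), and knockout MEP 22.2% (15.05% to 29.5%). The intervals meet and leave out the spread between libraries, and the difference between these shares was not tested. No double mutant GMP library was at hand, so the hypothesis stays open.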
